A study of Mus musculus with 10 samples.

How the data were processed

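RNA sequencing was carried out on mammary tumors of MMTV-PyMT mice, which develop mammary tumors from a viral oncogene driven in the mammary epithelium. Per the labels, the mice carried floxed alleles of Cxcr4, the receptor of the chemokine CXCL12, with Cre recombinase under the myeloid LysM promoter (here cKO), or were littermates without Cre (here control). Tumors were taken at 15 weeks. The macrophage table holds 3 cKO and 3 control libraries of tumor cells sorted on F4/80 and CD11b, and the whole-tumor table holds 2 cKO and 2 control libraries. The 6 mice are numbered in the labels, and 4 of them gave a library to both tables. Per the labels' protocols, ribosomal RNA was depleted by blocking oligonucleotides and not by selecting poly(A) RNA, so nuclear and small structured RNAs remain in the libraries. Per the submitters' processing notes, STAR 2.7.8a and Partek were used, and GRCm38 (mm10) was named as the build.

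The deposited values are named normalized counts, but they are on a log2 scale: 2 to the power of each value, minus 1, summed to 1e+06 in every library. Each deposited value is therefore log2(CPM + 1), where CPM is the count scaled to a library total of 1e+06 over listed genes. This was read from the values, since the deposited tables state no formula. The tests had been planned for linear values with a pseudocount of 1, and the deposited log2 values are already on that scale, so they were used without a further logarithm. Steps between low values gave the worth of a single read and hence the depth, 14.4 to 25.2 M reads in the macrophage libraries and 34.2 to 53.4 M reads in the tumor libraries (M, 1e+06). Within a tolerance of 0.1 read, 86.5% to 88.4% of low macrophage values and 86.9% to 89.0% of low tumor values came out as whole reads. This is under the 95% set for whole reads, so no count test was run. Genes were listed where their reads summed over a table to 10 or more, with no exception, which left 23202 genes in the macrophage table and 19720 in the tumor table. Gene positions in the tables do not match GRCm38: 2.19% and 2.29% of the genes found by identifier in the GENCODE vM21 annotation had the same start, so positions given here come from that annotation by gene identifier.

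A gene listed at 0 in a library allows up to 0.119 to 0.208 CPM (3 reads) in the macrophage libraries and 0.0562 to 0.0878 CPM in the tumor libraries. These limits cover counting error only. Among genes at 1 to 2 CPM in the other libraries of a table, 24.5% to 56.3% had under 3 reads in a macrophage library and 36.5% to 47.8% in a tumor library, which includes differences between mice. Reads per weakly expressed gene, used as a measure of library complexity, are the most frequent number of reads among detected genes with a mean under 5 CPM in the other libraries of the table.

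Each table was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(CPM + 1), cKO minus control, for genes with a mean of at least 1 CPM over the table. Fold changes are on that scale, which understates changes of weakly expressed genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The labels speak of pairs of tumors matched in size without naming the partners, so no pairing term was used. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Tests were also run on simulated log2 values with the moderated spread of the real genes, drawn independently for each gene and library. The 200 genes changed were taken only from those at 5 CPM or more on the mean log2 scale. Recovery of weaker genes, or with variation shared between genes, was not simulated. In the macrophage design, with 16304 genes, 15% of genes changed 2-fold, 78.5% of those changed 4-fold and 93.5% of those changed 8-fold were recovered. In the tumor design, with 14630 genes, 9%, 68.5% and 83.5% were recovered at those sizes.

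The gene lists, the tests and most alternatives were fixed before the data were examined. Genes are named by a fixed rule: Cxcr4, Cxcl12, Lyz2 and Ackr3; then, per direction, 8 genes with a mean of at least 5 CPM and non-overlapping groups, taken from genes past the threshold or, since none passed, by the lowest unadjusted p; and up to 4 members of each list past the threshold and 2 of other lists. Predicted gene models and pseudogenes were left out of the second part. A result that the rule picked in tumors is not reported here. Alternatives were other pseudocounts (0.1 and 5), other expression filters, rescaling by trimmed mean (TMM) or median-ratio factors, eBayes without the trend, and each library left out in turn. Library weights, scaling to protein-coding genes, gene classes by biotype and list tests on the 4 mice shared by both tables were added after the data were seen. Overlap between genes was read from the positions within each deposited table. The use of strand in counting was not given in the sources used here, so overlapping genes on either strand are treated as uncertain. Figures were drawn with matplotlib 3.10.9.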

Results

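The libraries describe sorted tumor macrophages and whole mammary tumors of MMTV-PyMT mice with and without a Cre-driven deletion of Cxcr4 in myeloid cells. The sorted cells came from 3 mice labelled cKO (numbers 725, 746 and 867) and 3 controls (706, 720 and 775). The tumors came from 2 of those cKO mice (725 and 746) and 2 of the controls (706 and 720). Each library is from a different mouse within its table. Depth, inferred from the steps between low values, was 14.4 M reads in the control 706 macrophage library and 20 to 25.2 M reads in the other 5 (M, 1e+06). The 4 tumor libraries held 34.2, 34.9, 35.4 and 53.4 M reads. Values are counts scaled to a library total of 1e+06 (CPM), and differences are log2 differences of CPM + 1, cKO minus control.

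Cxcr4, the targeted gene, was not lower in the libraries labelled cKO. Its level in macrophages was 77.1 ± 76.8 CPM (SD, n = 3) in the libraries labelled cKO and 68.0 ± 61.6 CPM (SD, n = 3) in the controls. The 3 libraries labelled cKO held 24.1 CPM (mouse 867), 41.9 CPM (725) and 165.2 CPM (746), and the controls held 14.45 CPM (706), 54.3 CPM (775) and 135.4 CPM (720). The log2 difference of 0.21 had a standard error of 0.59 and a 95% interval from -1.02 to 1.44 (limma, adjusted p = 0.9998). Its sign turned to -0.62 without control 706 and to -0.57 without cKO 746. In whole tumors Cxcr4 was at 52.7 ± 6.83 CPM (SD, n = 2) in the libraries labelled cKO and 31.6 ± 2.52 CPM (SD, n = 2) in the controls, a log2 difference of 0.72 (SE 0.29, limma adjusted p = 0.819). Macrophages gave no clear direction for the targeted gene. Tumors labelled cKO were higher without passing the test. Only myeloid cells were to lose Cxcr4, and a whole-tumor value sums all cells, so it cannot test the deletion. Every direction below is therefore that of libraries labelled cKO, not of cells shown to lack Cxcr4.

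Cxcr4 (ENSMUSG00000045382) lies on the minus strand of chromosome 1, from 128588199 to 128592293 in GRCm38. Its main transcript has an exon of 102 bases and an exon of 1703 bases. The labels do not say which part is floxed, and the tables give a single value for the whole gene, so reads inside and outside a deleted part cannot be separated. Lyz2, the gene whose promoter drives Cre in LysM-Cre mice, was nearly unread: 2.23 ± 1.82 CPM in control macrophages and 4.41 ± 2.98 CPM in those labelled cKO (SD, n = 3 each). Its neighbor Lyz1 held 108 to 645 CPM in the same libraries. Only 5.96% of 75-base stretches of Lyz2 occur in Lyz1. Cxcl12, the ligand, was at 19.6 ± 26.7 CPM in control macrophages and 48.6 ± 58.2 CPM in those labelled cKO (SD, n = 3 each), and Ackr3, its second receptor, was at 18.8 ± 7.73 and 28.3 ± 5.72 CPM. Neither passed the test (limma adjusted p = 0.9998 for both). In tumors the 2 genes differed by -0.09 and 0.02 log2 units, and the sign for Ackr3 turned under other scalings. The tumor difference of Cxcl12 came mainly from cKO 746 (66.8 CPM), with 75.5 CPM in cKO 725 and 75.9 CPM in each control.

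**Figure D1:**
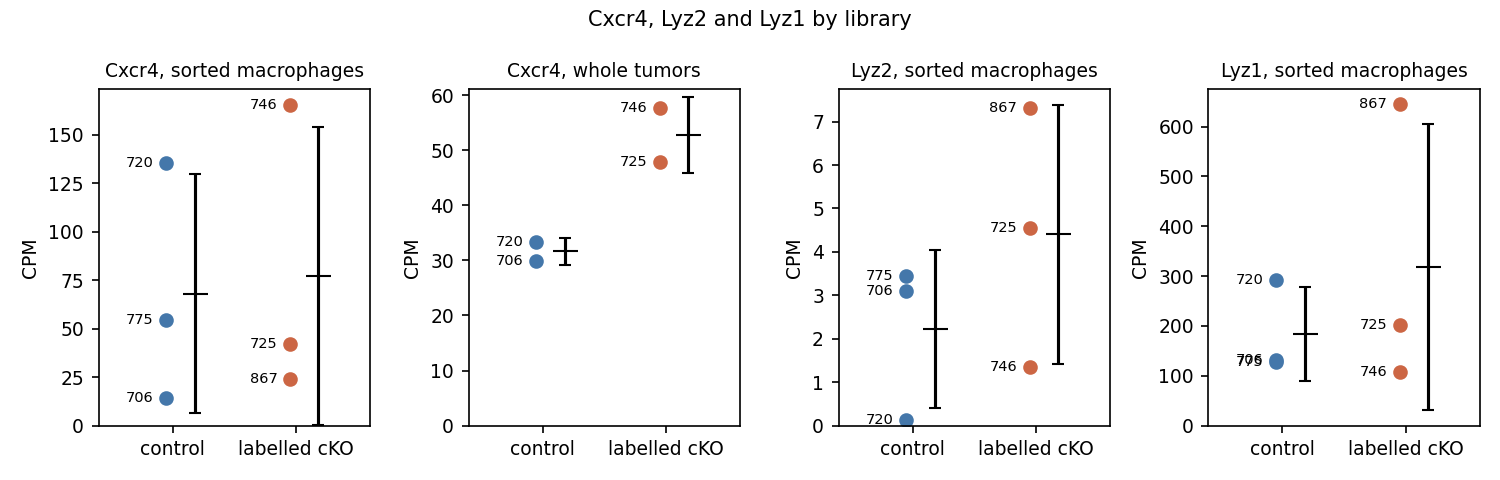
Cxcr4, Lyz2 and Lyz1 in CPM for each library, labelled by mouse number, with the mean and SD of each group beside the points. Cxcr4 spans 14.45 to 165.2 CPM in macrophages with overlapping groups, and in tumors both libraries labelled cKO (47.9 and 57.6 CPM) lie above both controls (29.8 and 33.4 CPM).

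The sorted cells carried macrophage transcripts far above the whole tumor, together with abundant epithelial transcripts. Adgre1, which encodes F4/80, was at 429 ± 117 CPM in the 6 macrophage libraries and 23.6 ± 4.63 CPM in the 4 tumor libraries. Itgam, which encodes CD11b and overlaps another protein-coding gene in the tumor table, was at 107 ± 52.3 and 5.97 ± 3.21 CPM, and Csf1r, the receptor for the macrophage growth factor CSF1, at 361 ± 110 and 17.5 ± 1.45 CPM. Epcam, an epithelial adhesion gene, was at 462 ± 102 CPM in macrophage libraries and 374 ± 60.4 CPM in tumors, and the keratin Krt8 was at 364 ± 107 and 60.8 ± 8.64 CPM. The milk casein Csn3 was at 2955 ± 1120 CPM in macrophage libraries and 5261 ± 1015 CPM in tumors (all SD, n = 6 and 4). The tables were normalized separately, and protein-coding genes took 67.6% to 80.1% of reads in macrophage libraries against 49.7% to 56.5% in tumor libraries, so these levels were not tested against each other. When scaled to protein-coding genes, the order for Epcam reversed, at 609 CPM in macrophage libraries and 714 CPM in tumors. Adgre1, Itgam, Csf1r, Krt8 and Csn3 kept their order. Small nuclear RNA took 2.05% to 6.76% of reads in macrophage libraries and 15.6% to 24.03% in tumor libraries.

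**Figure D2:**
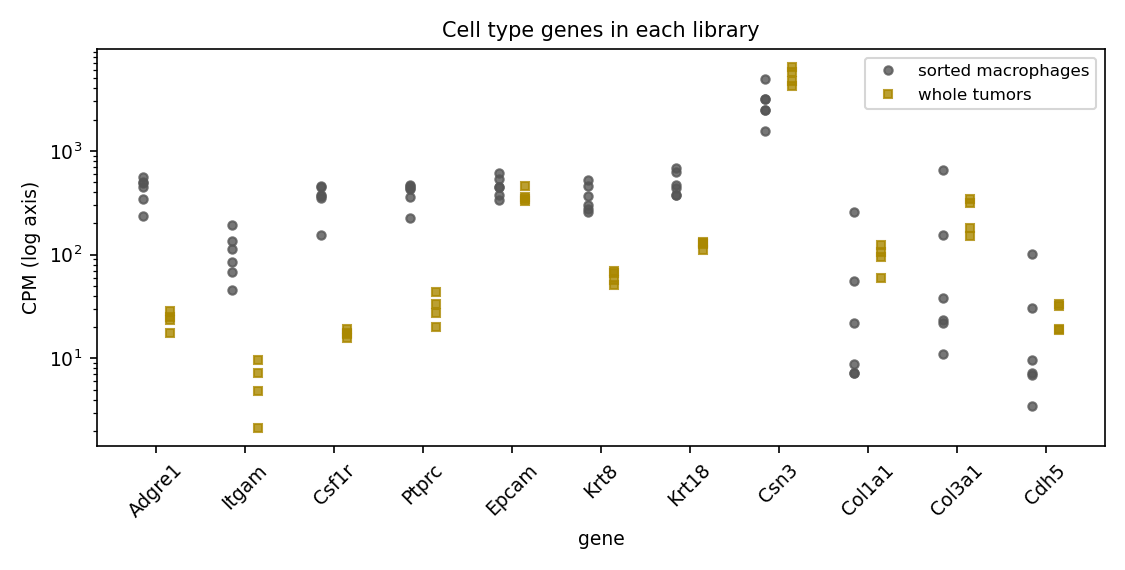
CPM of macrophage, epithelial, collagen and endothelial genes on a log axis, with a point for each of the 6 macrophage and 4 tumor libraries. Adgre1, Itgam, Csf1r and Ptprc are higher in every macrophage library than in every tumor library, while Epcam overlaps between the tables, and Col3a1 ranges from 11.05 to 652 CPM among macrophage libraries.

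The macrophage comparison asks what loss of Cxcr4 in myeloid cells does to the transcriptome of macrophages in the tumor. As groups, collagen and stroma genes, pericyte genes and genes of antigen presentation by MHC class II were higher in the macrophage libraries labelled cKO, and genes of cholesterol synthesis were lower. The 4 calls rest on the preset correlation, and each was lost with an estimated correlation (adjusted p = 0.940 with an estimated correlation for all 4) and with fry (adjusted p = 0.963). Of 23 tested collagen and stroma genes, 20 had a positive difference and 3 a negative one, with a median of 0.80 log2 units (camera adjusted p = 4.2e-05, but unadjusted p = 0.238 with an estimated correlation). None passed the gene test over all genes or adjusted over the list alone. Col5a1, a fibrillar collagen, was at 3.28 ± 5.60 CPM in controls and 19.8 ± 22.5 CPM in libraries labelled cKO. Sparc, a matrix-binding protein, was at 138 ± 173 and 273 ± 246 CPM, Col6a3 at 19.5 ± 27.7 and 45.7 ± 49.0 CPM, and Eln, which encodes elastin, at 2.06 ± 1.73 and 7.91 ± 4.13 CPM (SD, n = 3 each). The wide spreads came mainly from mouse 867, whose collagen genes lay 2.49 log2 units above the control mean, and from control 775, at 1.36. Endothelial and fibroblast genes lay high in the same 2 libraries, at 2.34 and 1.77 in 867 and at 1.34 and 1.04 in 775. Without 867 the collagen call was lost (median 0.043, adjusted p = 0.950), and without control 706 likewise (median 0.26, adjusted p = 0.389). The median was 1.79 without control 775, 1.23 without cKO 725 and 1.35 without cKO 746. Among the 4 mice other than 775 and 867 the list was past the threshold (median 0.88, camera adjusted p = 0.000153, unadjusted p = 0.197 with an estimated correlation).

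All 13 MHC class II genes had positive differences, with a median of 0.52 log2 units (camera adjusted p = 0.00176, unadjusted p = 0.219 with an estimated correlation). H2-DMa, which loads peptides onto class II molecules, was at 231 ± 130 CPM in controls and 322 ± 14.2 CPM in libraries labelled cKO. H2-Eb1 was at 546 ± 330 and 713 ± 206 CPM, H2-Ob at 3.70 ± 4.02 and 9.47 ± 6.75 CPM, and H2-Oa at 0.996 ± 1.72 and 5.43 ± 4.92 CPM (SD, n = 3 each). Control 775 had low class II genes, at -0.96 log2 units from the control mean, and low macrophage identity genes, at -0.89. Without it the median for class II was -0.11 (camera adjusted p = 0.949), and without cKO 725 the call was also lost (median 0.42, adjusted p = 0.0962), as it was without the trend (0.0693) and among the 4 mice other than 775 and 867 (median 0.14, adjusted p = 0.184). The median was 0.94 without control 706 and 0.26 without cKO 746. Pericyte and smooth muscle genes had a median of 0.61, with 8 of 9 positive (camera adjusted p = 0.0308, unadjusted p = 0.243 with an estimated correlation). Rgs5, a pericyte gene, was at 16.3 ± 23.8 and 49.9 ± 67.1 CPM, and Mcam at 23.4 ± 11.2 and 34.9 ± 10.8 CPM. The pericyte call was lost without cKO 867 (median 0.23, adjusted p = 0.761), control 706 (0.51, 0.338) or control 720 (0.53, 0.0975), with a mean of at least 5 CPM (0.0871), without the trend (0.0953), with library weights (0.55, 0.126) and among those 4 mice (0.50, 0.132). Its median was 1.20 without control 775 and 1.15 without cKO 725. Of 24 cholesterol synthesis genes, 17 were lower, with a median of -0.21 (camera adjusted p = 0.0304, unadjusted p = 0.110 with an estimated correlation). Sc5d, a desaturase of the pathway, was lower in all 3 libraries labelled cKO, at 28.0 ± 5.84 against 48.5 ± 14.2 CPM, and Fdft1, which makes squalene, was at 3.45 ± 2.06 against 9.93 ± 4.83 CPM (SD, n = 3 each). The cholesterol call was lost without control 775 (median -0.27, adjusted p = 0.251) and without cKO 746 (median -0.11, adjusted p = 0.379), with a mean of at least 5 CPM (-0.17, 0.0547), without the trend (0.0693) and among those 4 mice (-0.29, 0.118).

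**Figure D3:**
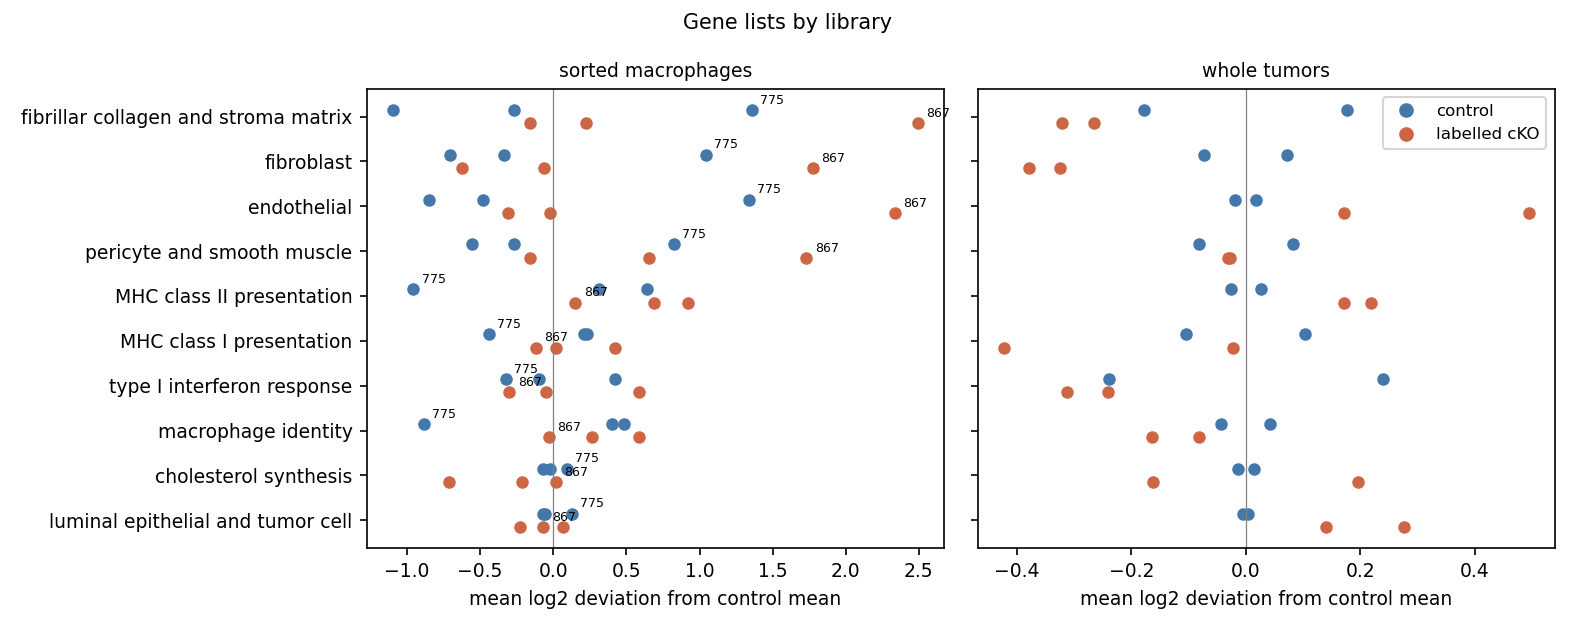
Mean log2 deviation of 10 gene lists from the control mean, with a point for each library and separate horizontal scales for the macrophage and tumor panels. In macrophages the collagen, fibroblast, endothelial and pericyte lists are highest in mouse 867 and next highest in control 775, and in tumors both libraries labelled cKO lie below both controls for collagen and fibroblast genes.

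No single gene passed the threshold in macrophages. Of 16304 genes tested with limma, 0 had an adjusted p under 0.05 (lowest 0.9998), and 428 had an unadjusted p under 0.05, of which 250 were higher and 178 lower in libraries labelled cKO. Chance alone would give about 815. Every library labelled cKO lay above every control for 617 genes and below for 563, or 7.24% of genes, where chance gives 10%. Among the genes named by rule, none of which passed, Gbp6, an interferon-induced GTPase of a family with near-identical copies, was at 5.96 ± 8.34 CPM in controls and 23.6 ± 7.03 CPM in libraries labelled cKO, a log2 difference of 2.59 (95% interval 1.10 to 4.08). Grap2, an adaptor protein of immune receptor signaling, was at 15.5 ± 8.16 and 43.1 ± 13.99 CPM, a difference of 1.52. Rp2, R3hdm2, Triobp, Gas2l1, Rtl8a and Cox7a2 were also higher in all 3 libraries labelled cKO, by 0.82 to 2.42. Tufm, a mitochondrial elongation factor, was at 10.6 ± 3.28 CPM in controls and 1.68 ± 1.91 CPM in libraries labelled cKO, a difference of -2.32. Dennd2d was at 37.4 ± 1.20 and 18.2 ± 1.56 CPM, and Mpzl2, an epithelial adhesion gene, at 88.0 ± 10.6 and 47.9 ± 19.5 CPM (SD, n = 3 each). Cblc, Slf1, Ulk4, Mir677 and Atp6v1c2 were also lower in all 3, with differences from -1.53 to -2.35. Mir677 lies within Atp5b, and the spans of Gas2l1, Ulk4, Dennd2d, Atp6v1c2, Fdft1, H2-DMa and Clec9a overlap another protein-coding gene, so their values are uncertain. Those of Grap2, Mpzl2, Rp2, Triobp, Col5a1, H2-Eb1 and Mcam overlap a noncoding, pseudogene or unclassified one.

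Lists of macrophage states did not pass the list test. Macrophage identity genes had a median difference of 0.31 (camera adjusted p = 0.0566), tissue-resident macrophage genes 0.37 (0.149) and alternative activation genes 0.35 (0.149). Without control 775 the identity list passed downward (median -0.23, camera adjusted p = 0.0222). It passed upward without control 706 (0.49, adjusted p = 1.5e-05), control 720 (0.51, 0.000852) or cKO 867 (0.45, 5.6e-05) and with library weights (0.37, 0.0041), and its median was 0.055 without cKO 746 (0.501). The tissue-resident list passed upward without control 775 (0.52, 0.0222) or cKO 746 (0.69, 1.9e-05), and alternative activation without control 720 (0.60, 0.0148) or cKO 746 (0.79, 0.00363). Without cKO 867 their medians were -0.13 and -0.0090, without control 706 they were 0.24 and 0.20, and alternative activation had a median of 0.12 without control 775 and 0.58 without cKO 725. Lipid-associated macrophage genes had a median of -0.16 (0.324), and passed downward without control 775 (-0.39, 7.6e-05) and among the 4 mice other than 775 and 867 (-0.31, 0.0193). Among those 4 mice the call was lost by camera with an estimated correlation (unadjusted p = 0.0763, adjusted p = 0.917). The median of this list was 0.069 without control 706, -0.067 without control 720 and -0.0047 without cKO 867. Arg1, an arginase of alternatively activated macrophages, was at 70.9 ± 56.7 CPM in controls and 29.6 ± 11.3 CPM in libraries labelled cKO, and Irf4, a transcription factor of the same list, at 10.04 ± 6.68 and 31.8 ± 32.4 CPM. Csf1, the macrophage growth factor, was at 51.2 ± 33.5 and 99.6 ± 34.8 CPM, and Hbegf, an epidermal growth factor family member, at 182 ± 110 and 256 ± 61.6 CPM (SD, n = 3 each). Clec9a, a receptor of cross-presenting dendritic cells, was higher in all 3 libraries labelled cKO, at 8.75 ± 2.87 against 0.863 ± 0.811 CPM. Ly6d, the other member of the dendritic cell list named by rule, was lower in all 3, at 110 ± 14.6 against 168 ± 30.1 CPM, and the list had a median of 0.30 (0.139; 0.56 without control 720 and 0.16 without cKO 867). Inflammatory activation, monocyte, chemokine, interferon, angiogenic and hypoxia lists had medians between -0.02 and 0.24. Of these, chemokine genes passed upward without control 720 (0.37, 0.0210) or cKO 746 (0.26, 0.0104), and hypoxia genes downward without control 775 (-0.23, 0.00523). With a library left out, medians ranged from -0.23 (control 775) to 0.19 (control 706) for hypoxia, from -0.029 (control 775) to 0.41 (control 706) for inflammatory activation, from -0.15 (cKO 867) to 0.43 (cKO 725) for monocyte and from 0.0025 (control 775) to 0.37 (control 720) for chemokine genes. For the angiogenic list (median 0.13) and for oxidative phosphorylation (median 0.02) the camera test pointed downward, at adjusted p = 0.878 for both. The first median turned to -0.19 without control 775 and was 0.030 without cKO 746, and the second ranged from -0.088 without control 775 to 0.18 without cKO 867. Of 34 lists tested, 30 did not pass, at adjusted p from 0.0542 (endothelial) to 0.956 (milk and secretory epithelium). The endothelial list, with a median of 0.70, passed without control 775 (1.24, adjusted p = 1.7e-06), cKO 725 (1.015, 0.0384) or cKO 746 (1.29, 3.7e-06) and with a pseudocount of 5 (0.39, 0.0304), while its median was -0.50 without cKO 867, 0.075 without control 706 and 0.42 without control 720. Other lists passed with a library left out. Without control 775 these were fibroblast (0.71, 0.000788), basal epithelial (0.79, 0.0222), neutrophil (-0.70, 0.00256) and cell cycle genes (-0.25, 0.0208). Without cKO 746 they were dendritic cell (0.79, 0.00277) and cell cycle genes (-0.22, 0.0206), and without cKO 725 fibroblast (0.66, 0.0390) and epithelial-mesenchymal transition genes (0.41, 0.0489). Unfolded protein response genes passed without control 720 (0.23, 0.0307) or cKO 867 (0.20, 0.0423), and the list of the CXCL12 receptor axis without cKO 867 (0.55, 0.0451). The neutrophil list also passed among the 4 mice other than 775 and 867 (-0.70, 0.0193), but not by camera with an estimated correlation (unadjusted p = 0.0797, adjusted p = 0.917).

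The tumor comparison asks whether the whole tumor differs when its myeloid cells lack Cxcr4. Here collagen and fibroblast genes, type I interferon response genes and MHC class I genes were lower as groups in the libraries labelled cKO, again by the preset correlation alone. For MHC class I, cKO 725 (-0.02 log2 units from the control mean) lay between controls 706 and 720 (0.10 and -0.10). For interferon genes, cKO 746 (-0.2405) was level with control 706 (-0.2393). All 4 calls were lost with an estimated correlation (adjusted p = 0.785 with an estimated correlation) and with fry. Of 24 collagen and stroma genes, 18 were lower, with a median of -0.26 log2 units (camera adjusted p = 0.00162, unadjusted p = 0.170 with an estimated correlation). Of 18 fibroblast genes, 13 were lower, with a median of -0.40 (camera adjusted p = 0.00162, unadjusted p = 0.0529 with an estimated correlation). The lists share members, among them Col3a1, at 330 ± 19.4 CPM in controls and 168 ± 21.0 CPM in libraries labelled cKO, a log2 difference of -0.98 (95% interval -1.37 to -0.58, limma adjusted p = 0.584). Col3a1 was the only member of either list past the threshold when adjusted over the list alone, and none passed over all genes. Col1a2 was at 143 ± 34.7 and 84.0 ± 22.7 CPM, Lum, a collagen-binding proteoglycan, at 22.3 ± 0.396 and 9.34 ± 1.70 CPM, and Postn at 194 ± 55.8 and 130 ± 4.91 CPM. Eln went the other way, at 6.51 ± 4.78 in controls and 19.6 ± 3.45 CPM in libraries labelled cKO (SD, n = 2 each).

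Of 28 interferon response genes in tumors, 20 were lower, with a median of -0.32 (camera adjusted p = 0.00162, unadjusted p = 0.264 with an estimated correlation). Ifi44 was at 200 ± 44.3 CPM in controls and 134 ± 0.438 CPM in libraries labelled cKO, Rsad2, an antiviral enzyme, at 79.0 ± 28.3 and 46.4 ± 8.71 CPM, and Usp18 at 28.6 ± 11.9 and 14.4 ± 0.846 CPM. Of 14 MHC class I genes, 11 were lower, with a median of -0.32 (camera adjusted p = 0.0427, unadjusted p = 0.208 with an estimated correlation). B2m, the light chain of class I molecules, was at 514 ± 53.5 and 359 ± 77.0 CPM, and Erap1 was higher, at 88.6 ± 5.51 against 60.7 ± 1.16 CPM (SD, n = 2 each). None of the 4 calls was made without control 720, when the median was -0.055 for collagen (adjusted p = 0.567), -0.22 for fibroblast (0.215), -0.24 for interferon (0.567) and -0.35 for class I genes (0.215). The interferon call was also lost without cKO 746 (-0.29, 0.0521), and its median was -0.68 without control 706. The class I call was also lost without control 706 (-0.29, 0.200), without cKO 746 (-0.21, 0.350) and without the trend (0.136), and its median was -0.49 without cKO 725. The collagen median was -0.47 without control 706. In macrophages the interferon and class I lists had medians of 0.00 and 0.03 (camera adjusted p = 0.878 and 0.874), and both medians changed sign with a library left out. The interferon list passed upward without cKO 867 (median 0.22, adjusted p = 0.0384), and its median was 0.19 without control 720, 0.048 without cKO 725, -0.041 without control 706, -0.15 without control 775 and -0.22 without cKO 746 (adjusted p = 0.0616). The class I median was -0.22 without control 775, -0.14 without cKO 746 and 0.15 to 0.24 with any other library left out. Other scalings turned the interferon median to between -0.014 and -0.056, and scaling to protein-coding genes turned that of class I to -0.036.

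No gene passed the threshold in tumors. Of 14630 genes tested with limma, 0 had an adjusted p under 0.05 (lowest 0.492), and 856 had an unadjusted p under 0.05, of which 571 were higher and 285 lower in libraries labelled cKO. Chance would give about 732. Fewer genes were listed at 0 in cKO 725 and 746 (3282 and 3200) than in controls 706 and 720 (3785 and 4170). The excess of higher genes was not separated from this difference in detection. The groups did not overlap for 35.5% of genes, where chance gives 33.3%. Among the genes named by rule, Ank, a pyrophosphate transporter, was at 42.1 ± 5.82 CPM in controls and 101 ± 32.8 CPM in libraries labelled cKO, a log2 difference of 1.22. Ptx3, a soluble pattern recognition protein, was at 18.8 ± 1.66 and 50.5 ± 13.02 CPM, and Elapor1 at 105 ± 3.82 and 187 ± 12.98 CPM. Ago1, Tex261, Ralgapb and Sap18b, which has a near-identical paralog, were also higher, by 0.89 to 3.05. Cebpd, a transcription factor of inflammation, was at 47.7 ± 2.11 CPM in controls and 16.1 ± 2.47 CPM in libraries labelled cKO, a difference of -1.52. The milk casein Csn1s1 was at 33.995 ± 0.925 and 7.96 ± 5.44 CPM, a difference of -2.11, the transferrin receptor Tfrc at 212 ± 38.3 and 120 ± 11.01 CPM, and the small heat shock gene Hspb8 at 33.9 ± 3.62 and 11.3 ± 0.61 CPM. Snhg5 was at 434 ± 48.6 and 200 ± 100 CPM, the small nucleolar RNA Snord50a at 727 ± 103 and 404 ± 133 CPM, and Snord50b at 582 ± 70.5 and 332 ± 106 CPM (SD, n = 2 each). Snord50a and Snord50b differed by -0.88 and -0.84, and were lower in cKO 725 (310 and 257 CPM) than in cKO 746 (498 and 407 CPM). These 3 genes share their locus, since Snhg5 is the host of both small RNAs, and the spans of Ank, Ptx3, Cebpd and Erap1 overlap another protein-coding gene and those of Col1a2 and Elapor1 an unclassified one, so these values are uncertain. Adjusted p for these genes named by rule lay between 0.584 and 0.645.

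Other tumor lists did not pass. Skeletal muscle genes had a median of 1.04 and were high in cKO 725 alone, at 1.75 log2 units from the control mean (0.05 in cKO 746, camera adjusted p = 0.0875 for the list). That list passed without cKO 746 (median 1.96, adjusted p = 0.000984), with a pseudocount of 5 (0.0375), with median-ratio factors (0.0409), without the trend (0.0456) and when scaled to protein-coding genes (0.0455), and without cKO 725 its median was 0.46 and the test pointed downward (0.731). Luminal epithelial genes had a median of 0.14 (0.030 to 0.084 under other scalings) with 19 of 24 positive (0.197), among them Foxa1 at 23.2 ± 7.13 and 47.9 ± 16.9 CPM and Erbb2 at 21.2 ± 3.57 and 36.5 ± 7.47 CPM (SD, n = 2 each). Erbb2 overlaps the protein-coding gene Mien1, so its value is uncertain. Macrophage identity genes had a median of 0.03 but a mean of -0.12, and the test pointed downward (0.671). That median turned to -0.096 without control 706, to -0.098 without cKO 725 and to between -0.030 and -0.12 under other scalings, and was 0.12 without cKO 746. Cell cycle genes had a median of -0.19 (0.120), which was -0.033 without control 706, -0.10 without control 720, -0.035 without cKO 746 and -0.32 when scaled to protein-coding genes. Oxidative phosphorylation genes had a median of -0.13 (0.0895), which was 0.067 without cKO 746, -0.25 without control 706, -0.28 without control 720 and -0.22 when scaled to protein-coding genes, and the list passed downward without cKO 725 (-0.31, 0.0121). Endothelial genes had a median of 0.27 (0.470), which was 0.56 without cKO 725 and 0.16 with a pseudocount of 5. Of 35 lists tested, 31 did not pass. Lipid-associated macrophage genes passed downward without control 706 (-0.42, 0.00993), and without cKO 725 hypoxia genes passed upward (0.45, 0.0337) and adipocyte (-0.63, 0.0337), T cell (-0.81, 0.0411) and B cell genes (-0.89, 0.0337) downward. B cell genes also passed without the trend (-0.67, 0.0456).

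Fold changes in macrophages and in tumors were nearly unrelated. Across 13778 genes tested in both tables, Pearson's r was 0.019 and Spearman's rho 0.0082, and 51.2% of genes had the same sign. These are correlations across genes, which are not independent replicates. The median standard error of a fold change was 0.54 log2 units in macrophages and 0.57 in tumors, and no gene passed in either. Correlations near 0 could therefore arise even from shared changes, and they do not show that macrophages and tumors differ in response. With only the macrophage libraries of the 4 mice shared by both tables, r was 0.015, rho -0.0026 and the share of the same sign 48.5%, and with only the 2 macrophage libraries of the other mice they were 0.0099, 0.019 and 53.4%. At an unadjusted p under 0.05 in both, 13 genes were higher in both tables where independent lists would give 8.5, and 11 were lower in both where they would give 3.13. Another 2 were higher in macrophages and lower in tumors (4.05 by independence), and 6 the reverse (6.56). These independence values take no account of the 4 mice that gave a library to both tables, so they are not what chance alone would give for tables that share mice.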

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

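Tests of tumor-cell RNA in the sort, of stromal cells, of scaling, of library complexity and of other splits of the samples were chosen after the results they bear on, or values that gave them away, were seen, and only the test of matching by mouse was chosen before. Its spread over resampled genes was added afterwards. Of 32 named genes measured in both tables, 4 met a rule that every library labelled cKO moved from the control mean in opposite directions in macrophages and tumors. The difference between the tables was not tested. Of all 13778 genes in both tables, 10.6% meet the same rule, and 11.8% move alike in every library. Gbp6 differed by 2.89 log2 units between the tables, macrophages minus tumors. Grap2 differed by 2.28. Atp6v1c2 differed by -1.99, with a tumor value near 0 (0.04). Hspb8 differed by 1.88. None of the 34 gene lists met the rule. Groups of 3 and 2 libraries were too small to test single libraries as outliers.

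Cxcr4 was not lower in the macrophage libraries labelled cKO. A swap of labels between the groups in 1 table stays open: among the 24 ways to match the macrophage and tumor libraries of the 4 shared mice, the match by mouse number had the highest summed correlation of deviations (rank 1, a sum of 0.195), but the next (0.164) exchanged cKO 725 with control 706. Rank 1 met the bound set for arguing against a swap, yet that bound took no account of the spread: the lead of 0.0313 was below its SD of 0.0355 over 1000 resamplings of the genes, and the single correlations were weak, from 0.0256 to 0.0712 for the same mouse. RNA of tumor cells also stays open. The estimate used the Cxcr4 to Epcam ratio of the tumors labelled cKO for every macrophage library. By it, Cxcr4 was 0.613, 0.354 and 1.77 times the level from Epcam in cKO 725, 867 and 746. Controls were at 0.253 (706), 1.06 (775) and 1.67 (720) by the same ratio. That ratio was not taken from control tumors, which held less Cxcr4 (29.8 and 33.4 CPM against 47.9 and 57.6 CPM). The control values are therefore not a like comparison for the cKO values. The estimate assigns all Cxcr4 of the tumor to cells with Epcam. It therefore cannot separate RNA of tumor cells from Cxcr4 of the macrophages. Incomplete deletion, and reads from an undeleted part of the gene, stay open as untested.

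The collagen list was higher in macrophage libraries labelled cKO and lower in tumors labelled cKO, a difference that was not tested. Stromal cells in the sorts of mice 867 and 775 are a candidate source, although sorting on F4/80 and CD11b should remove them: 12 fibroblast genes outside the list lay 1.11 and 0.60 log2 units above the mean of the 6 libraries there and below it in the other 4, and Col3a1 was at 652 and 156 CPM there against 11.05 to 38.1 CPM in the others. Without both libraries the list was still past the threshold by the preset correlation (adjusted p = 0.000153), which met the bound set for arguing against this explanation. It is not taken as decisive, a stricter reading adopted only after that value was seen, because with an estimated correlation the unadjusted p was 0.197 and because the call was lost without 867 alone (adjusted p = 0.950). Among the remaining 4 libraries, control 706 stood apart, at -1.09 log2 units from the mean of the 3 controls. Control 720 was at -0.27, cKO 725 at -0.16 and cKO 746 at 0.23. Control 706 was also the shallowest macrophage library (14.4 M reads). Stromal cells therefore stay open, and so does an effect of genotype on matrix genes.

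The median difference of small nucleolar RNA genes, a class chosen after its values were seen, was negative in both tables, although in macrophages cKO 725 (0.20 log2 units from the mean of the 6 libraries) lay above controls 706 and 720 (0.11 and -0.00023) and only 746 and 867 (-0.44 and -0.37) lay below all controls. It was -0.38 log2 units over 208 genes in macrophages and -0.37 over 164 genes in tumors (unadjusted p = 0.108 and 0.0418 with an estimated correlation, 0.158 for each after adjustment over 8 class tests). When scaled to protein-coding genes the median was -0.45 and -0.49, but this cannot decide whether scaling to all listed RNA plays a part. In tumors protein-coding genes took 53.0% and 56.5% of reads in cKO 725 and 746, and 51.3% and 49.7% in controls 706 and 720. That scaling therefore had to lower the tumor difference. In macrophages the lowest such share was that of control 775 (67.6%). In macrophages library complexity may contribute: in both groups (2 of 2) the library with the fewest reads per weakly expressed gene, control 775 and cKO 725, had the highest small nucleolar RNA level, and the median was -0.15 without 775, -0.21 without cKO 746 and -0.64 without cKO 725. In tumors complexity, the mice shared between the tables and a genotype effect cannot be told apart with 4 libraries. Library cKO 725 had more reads per weakly expressed gene (76.8) than both controls (56.9 and 71.7), and cKO 746 had fewer (46.2). These numbers also depend on depth, and cKO 725 was the deepest library (53.4 M reads). Put in CPM, they were 1.44 in cKO 725 and 1.31 in cKO 746, below controls 706 (1.67) and 720 (2.06). On that scale the tumor groups run against the macrophage pattern, where the lowest library of each group had the highest small nucleolar RNA level. Small nucleolar RNA genes had median deviations from the mean of the 4 libraries of -0.24 (cKO 725) and -0.14 (cKO 746) log2 units. In the controls these medians were 0.11 and 0.24. The share of reads in small nucleolar RNA gave another order: 14.3% in cKO 725 and 10.9% in cKO 746, against 12.8% and 13.1% in controls 706 and 720.

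The splits of the 6 macrophage libraries into 3 and 3 number only 10, too few for a share under 0.05. For gene lists, among them the collagen list, the real split gave 4 past the threshold and the highest other split 21, and 8 of the 10 splits gave as many as the real one. For single genes the real split gave 0 and the highest other 3, and the comparison decides nothing, since all 10 splits must give at least 0. Splits that call several times the real number of lists point to structure among the libraries other than the label.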

How the results depend on the processing

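Tests with library weights, with scaling to protein-coding genes, of the correlation of fold changes with a library left out, and of lists, Cxcr4 and named genes in 4 mice were chosen after the data were seen. The planned edgeR and DESeq2 tests were not run, because the values did not prove to be whole reads. No paired analysis was possible because the cKO and control mice share no number and the labels do not name the matched partners. The number of macrophage genes past the threshold was 0 under the other pseudocounts, filters, scalings, weights and moderation (261 to 636 at an unadjusted p under 0.05 with limma), 0 to 3 with a library left out, and 2 among the 4 mice with a tumor library, where fewer samples were used. Without control 775 the genes were Sparc (log2 difference 2.45, adjusted p = 0.0458), Amd2 and Gm4735. Rps13-ps1 passed without control 706 and Ccdc152 without cKO 867, and Ccdc152 and Gm4735 passed among the 4 mice. All but Sparc were named after their values were seen, and they are uncertain: Rps13-ps1 and Gm4735 are pseudogenes, Amd2 has a close paralog and Ccdc152 overlaps Selenop. The number of tumor genes was 0 under every alternative run (321 to 1025 at an unadjusted p under 0.05 with limma), including each library left out, where the lone library is assumed to vary like the other group. The Cxcr4 difference in macrophages ranged from -0.62 without control 706 and -0.57 without cKO 746 to 0.95 without control 720, and in tumors from 0.59 to 0.85. The 4 macrophage lists became 2 with a mean of at least 5 CPM, 1 without the trend, 0 with an estimated correlation, 0 with fry and 3 to 11 with a library left out. The 4 tumor lists became 5 without the trend, where MHC class I was lost (adjusted p = 0.136), 0 with an estimated correlation, 0 with fry and 0 to 9 with a library left out. The cause was not tested. With a library left out, the macrophage MHC class II median ranged from -0.11 (control 775) to 0.94, and the collagen median from 0.043 (cKO 867, where the test pointed downward) to 1.79. The tumor difference of Ackr3 turned to -0.042 with TMM factors, -0.062 with median-ratio factors and -0.098 when scaled to protein-coding genes, and ranged from -0.16 to 0.19 with a library left out (-0.14 without control 706). Scaling to protein-coding genes moved the median difference of all tumor genes from 0.09 to -0.03. The correlation of fold changes was 0.040 with a mean of at least 5 CPM and 0.0054 to 0.032 with a macrophage library left out. Apart from Cxcr4, 41 named genes in macrophages and 31 in tumors kept their direction and their side of the threshold under the alternatives run, with the exceptions of Sparc in macrophages and Ackr3 in tumors. This was largely fixed by how the genes were picked, so it is not evidence that they are stable. Groups that do not overlap keep their direction with a library left out, and named list members had the lowest p of their list. In simulations of these designs, 2-fold changes were recovered for 15% (macrophages) and 9% (tumors) of the changed genes, all at 5 CPM or more. Changes of that size would therefore mostly be missed.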

Other observations

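The tests of gene classes given here were all chosen after the values were seen. Transcripts of the mitochondrial genome had a median difference of 0.82 log2 units in macrophages, with 17 of 19 positive (unadjusted p = 0.113 with an estimated correlation), and of 0.12 in tumors. The tumor median was 0.015 without control 706, 0.33 without control 720, 0.24 without cKO 725 and 0.038 to 0.058 under other scalings. They made up 5.05%, 2.73% and 3.44% of reads in the macrophage libraries labelled cKO (mice 725, 746 and 867) and 1.03%, 4.09% and 1.78% in controls 706, 720 and 775. Without control 720 the macrophage median was 1.30 (unadjusted p = 0.0276 with an estimated correlation) and without control 706 it was 0.31. In tumors the share was 1.29% to 1.43% in every library.

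Small noncoding RNAs took a large part of the tumor reads. Rn7sk, a nuclear RNA that restrains transcription elongation, was at 9.43% to 13.4% of reads in tumors and 1.89% to 4.34% in macrophage libraries. Host genes of small nucleolar RNAs had a median difference of -0.51 in tumors, with 12 of 15 lower (unadjusted p = 0.0505 with an estimated correlation), and -0.05 in macrophages, with 9 of 17 lower. Without cKO 725 the tumor median was -0.30. The macrophage median of host genes was -0.080 to -0.087 under other scalings, turned to 0.038 without control 706 and 0.099 without control 775, and was -0.096 without control 720, -0.12 without cKO 725, -0.13 without cKO 746 and -0.019 without cKO 867. Small nuclear RNA genes had negative median differences in both tables, -0.31 in macrophages (24 of 27 lower, unadjusted p = 0.117 with an estimated correlation) and -0.44 in tumors (23 of 27 lower, 0.119). The macrophage median of small nuclear RNA genes was -0.091 without control 775 and -0.55 without control 720 (unadjusted p = 0.00838 with an estimated correlation).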
